A study of Rousettus aegyptiacus with 4 samples.

How the data were processed

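Circulating leukocytes of the Egyptian rousette bat (Rousettus aegyptiacus) were measured by droplet-based single-cell RNA sequencing of transcript 3' ends (10x Genomics) in 4 libraries, each pooled from 3 animals. Per the labels, the groups were whole blood of adults (older than 3 years), whole blood of juveniles (about 1 year old), and whole blood and peripheral blood mononuclear cells (PBMC) of a separate set of 3 animals, 1 adult and 2 subadults. The adult and juvenile libraries were taken and prepared in parallel on a common day, and so were the other two libraries. Red cells of whole blood were lysed repeatedly; PBMC were collected from a density gradient; all cells passed a strainer and a sort that depleted platelets.

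The values deposited by the authors are counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalisation. Cell Ranger 3.1.0 is credited by the file headers and the submitters' processing notes. The genome build and gene annotation behind the counts are not given in the sources used here. Every barcode had at least 500 UMIs, so the matrices hold called cells. A reference gene table of this species was used for gene names and for the order of neighbouring genes only. The matrices held 24328 genes, of which 16223 had a symbol and 8105 a LOC identifier. Of the symbols, 15931 were in the reference table, as were all 8105 LOC identifiers.

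The deposited barcodes numbered 5631 for adults, 6360 for juveniles, 4250 for whole blood of mixed ages and 6002 for PBMC, 22243 in all. Their total UMIs were 18693608, 21722415, 17215904 and 22144377. Kept barcodes had at least 200 genes, at least 500 UMIs and less than 15% mitochondrial UMIs. Doublets were scored per library with Scrublet (expected rate 5%), whose automatic threshold marked 108, 285, 74 and 159 barcodes; these 626 were removed. The kept cells numbered 5343, 5848, 3959 and 5624 (20774), with median depths of 2409, 2997, 3512 and 3116 UMIs and medians of 1085, 1383, 1521 and 1400 genes.

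Cells of all libraries were clustered together without batch correction. Counts were scaled per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components and 15 neighbours gave a shared-neighbour graph for Leiden clustering at resolution 1 (10 iterations, seed 0). Mitochondrial, ribosomal protein, haemoglobin cluster (8 genes, 5 of them without a symbol) and 72 receptor and immunoglobulin segment genes were left out of clustering, as were 11 genes near SRY or CHIC1 (9 of them 3 to 87 places from SRY in the reference gene order, here SRY neighbours), 184 genes in all. The tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9, and R 4.3.3 with edgeR 4.0.16.

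Clusters were named with 13 marker lists: neutrophil, monocyte, conventional and plasmacytoid dendritic cell, B cell, plasma cell, T cell, NK cell, basophil or mast cell, eosinophil, platelet, erythroid cell and progenitor. A cluster took the class of its highest mean log2 marker ratio against the other clusters, provided that this score was at least 0.25, at least 3 markers were seen in 1% or more of its cells at 2 times the level elsewhere, the runner-up class had at most 0.5 of the score, and its 10 leading genes (in at least 5% of cells) did not hold more markers of another class than of its own (the MMP8-led cluster held 4 of its own and 1 of another). A cluster whose median depth was under its library's median divided by 3 also needed a marker of its own among its leading genes. Of 19 clusters, 15 were named as neutrophil-, monocyte-, conventional dendritic-, plasmacytoid dendritic-, B-, T- or NK-like. No cluster took the plasma cell, basophil, eosinophil, platelet, erythroid or progenitor name. The 4 unnamed clusters are called by a leading gene: RNASE1-high, ADGRE1-high, PTGS2-high (low UMIs) and ABCA8-high. T- and NK-like cells together, and B-like cells, were clustered again at resolution 0.8, and their subsets are called by leading genes; subset shares are compared where the subset had at least 100 cells and the median size of the log2 ratios of those genes was at most 0.57, a limit set after these values had been seen. Single leading genes of compared subsets differed by up to 3.03.

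There was 1 library per group, so no test between groups and no p-value was possible, and a value cannot be separated from the animals, day and preparation of its library. Shares have Wilson 95% intervals and their differences Newcombe intervals. Gene levels are UMIs summed over the cells of a class and library as CPM (the UMIs of each class and library scaled to an equal total) with exact Poisson intervals. Ratios are log2 ratios of CPM plus a pseudocount of 5, with an interval that combines both Poisson intervals. They are given for classes and clusters with at least 100 cells in both libraries, except where juvenile cells are split by kind or B-like cells by subset. These intervals cover counting error only, while those of gene list medians cover the spread between list members. In the smallest lists the latter are the full range of members and cover less than 95%. No interval covers differences between animals. Where a gene had 0 UMIs, the limit is that of 3 counts.

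The comparisons, cell filter, marker lists, 19 gene lists, rule for named genes and first alternatives were chosen before the data were examined. Named genes were the 3 highest and 3 lowest log2 ratios of a class for juveniles over adults, and the 2 highest and 2 lowest for PBMC over whole blood. They needed a symbol, a CPM of at least 50 and at least 30 UMIs in the higher library and at least the CPM of the class where the gene was highest divided by 3; haemoglobin, mitochondrial and ribosomal protein genes were left out. Members of a list with large ratios were named besides. Some genes and a subset are not reported here. A gene list needed 3 members with a CPM of at least 10 in either library. Its value is the median log2 ratio with an order-statistic interval, beside its percentile among 10000 random lists of like size and expression. The lists were interferon-stimulated genes, MHC class I and class II presentation, cytotoxic effector, naive and central memory T cell, early B cell, memory and activated B cell, neutrophil granule and immaturity, mature neutrophil, inflammatory and NF-kB, immediate early and heat shock, pattern recognition receptor, Fc and complement receptor, proliferation, ribosomal protein and nuclear oxidative phosphorylation genes, and the neutrophil, erythroid and platelet markers as read in other cells. Medians that rest on members with 0 UMIs are also given with those members at the limit of 3 counts. Listed genes absent by name from the matrices could not count as members. The matrices held 7 of 18 MHC class II presentation, 12 of 25 neutrophil granule and immaturity, and 10 of 16 mature neutrophil genes.

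Some choices were made after the data had been seen. B cell and plasma cell markers were counted as a common lineage in the naming, since B-like clusters carried both. The limits of 0.25 and 0.5 for the score and the runner-up were set at that stage, and the runner-up limit kept the ABCA8-high cluster out of a class. The genes near SRY and CHIC1, the names of the unnamed clusters, the wider denominator without the ADGRE1-high and PTGS2-high clusters and the form of the intervals were also chosen then. Juvenile cells were called by kind: CHIC1-neighbour kind with at least 1 UMI of a non-coding RNA near CHIC1 and none of the SRY neighbours (the most widely found SRY neighbour aside), SRY-neighbour kind with SRY-neighbour UMIs and none of that RNA. The test within B-like subsets was repeated with subsets formed without the list's own genes after its first value had been seen.

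The alternatives were no cell filter, at least 500 genes, doublets kept, resolutions 0.5 and 2, each library clustered alone, the class of the highest marker score per cell, pseudocounts of 1 and 20, edgeR's TMM factors, subtraction of the library profile as RNA from outside the cell, every cell thinned to 500 UMIs, list members with a CPM of at least 50, lists without markers of other classes, and subset resolutions of 0.4 and 1.5. Added after the data were seen were the genes near SRY and CHIC1 kept in clustering, juvenile cells of the CHIC1-neighbour kind alone, and the wider denominator. The share of outside RNA was estimated from neutrophil markers in B- and T-like cells as 1.34% of UMIs for adults, 1.52% for juveniles, 1.11% for whole blood of mixed ages and 2.60% for PBMC.

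The calculations were tested on simulated data with 200 changed genes per class among 24328. These counts were drawn with Poisson counting error only, which is the error that the intervals assume. The test thus checks the calculation, and not whether the intervals cover the spread between cells or animals. The true ratio lay inside the interval for 94.0 to 96.1% of genes per class. All genes changed by a factor of 2 or 4 were found in B-, T-, NK-, monocyte- and neutrophil-like cells. Of genes made 2 times higher, 86% were found in ADGRE1-high and 68% in PTGS2-high cells; of genes lowered by the same factor, 70% and 58%, and 84% in RNASE1-high cells of the age comparison. Outside RNA put in at 5% was estimated as 4.91 to 5.16%, and at 1% as 0.454 to 1.07%. The index sequences listed beside the matrices were not used here.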

Results

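Blood leukocytes of a fruit bat, the Egyptian rousette, were compared between adults and juveniles in whole blood, and between whole blood and the mononuclear fraction (PBMC) of another 3 animals. Each group was 1 library of 3 pooled animals, without replicates, so the values describe these libraries. Besides age, the first pair of pools differed in 9 genes listed near SRY (3 to 87 places away), the sex-determining gene of placental mammals, with 3 UMIs in the adult library and 28250 in the juvenile library.

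Adult blood was rich in neutrophil-like cells, the granule-bearing phagocytes of acute inflammation, and juvenile blood was rich in B-like cells, the lineage that makes antibodies. Neutrophil-like cells were 34.4% (95% interval 33.2 to 35.7%) of the adult library and 10.8% (10.0 to 11.6%) of the juvenile library, a difference of −23.6 percentage points (−25.1 to −22.1). B-like cells rose from 9.17% (8.43 to 9.97%) in adults to 38.6% (37.4 to 39.9%) in juveniles, by 29.5 points (28.0 to 30.9). T-like cells were lower in juveniles, at 16.4% against 26.8% (−10.4 points, −12.0 to −8.92), and NK-like cells, the killers of infected cells, were higher, at 17.5% against 9.66% (7.85 points, 6.60 to 9.11). Monocyte-like cells made up 3.74% of adult and 2.29% of juvenile cells (−1.45 points, −2.10 to −0.819). Among cells that were not neutrophil-like, B-like cells were still 14.0% in adults and 43.3% in juveniles, and T-like cells 40.9% and 18.3%. Whole blood of mixed ages, from other animals, had 10.1% neutrophil-like, 32.1% B-like, 13.4% T-like, 21.3% NK-like and 4.45% monocyte-like cells.

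The neutrophil-like cells of the libraries lay in different clusters. A cluster led by the granule collagenase MMP8 and the calcium-binding alarmins S100A9 and S100A12 had 925 adult cells among its 935, so it coincides with the adult library. A cluster led by the decoy receptor IL1R2 and by SERPINE2 had 652 adult and 106 juvenile cells. The cluster led by G0S2, EGR2, OSM and CXCL8 held 262 adult and 520 juvenile cells, most of the juvenile class, and 362 of the 399 neutrophil-like cells of mixed-age blood. Conventional dendritic-like cells were 0.318% of adult and 0.445% of juvenile cells, and plasmacytoid dendritic-like cells 0.112% and 0.171% (differences 0.126 points, −0.111 to 0.365, and 0.0587 points, −0.0951 to 0.215). The conventional dendritic-like difference ranged from −0.635 with at least 500 genes per cell to 0.712 with classes called per cell, a setting that gave 7.84 points for plasmacytoid ones, so neither direction is settled. Among juvenile cells of the kind that carried an RNA near CHIC1, a split chosen after the data were seen, NK-like cells were an estimated 28.5% and monocyte-like cells 2.87%, against 9.70% and 3.76% of adult cells, if the RNA was found as often as in adults. At clustering resolution 0.5, which left many T-like cells unnamed, the T-like difference was −3.68 points, and with classes called per cell the monocyte-like difference was −2.38 points.

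**Figure D1:**
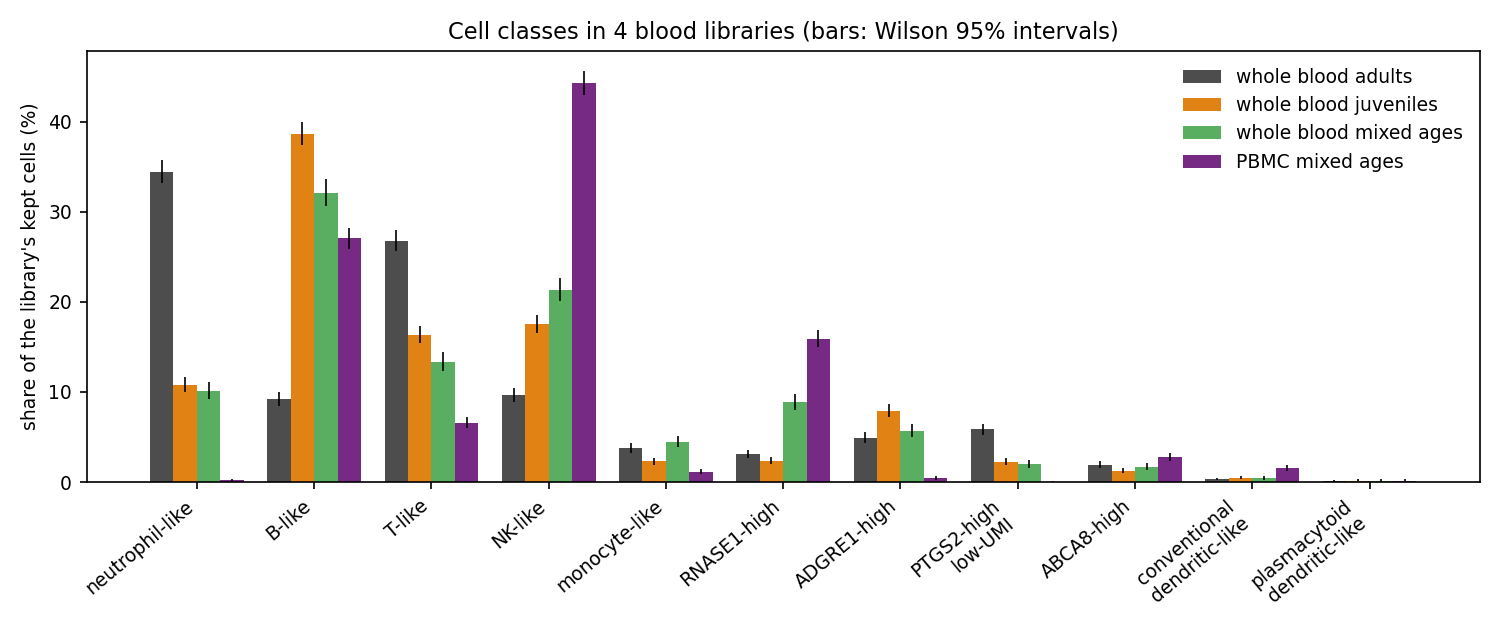
Share of the kept cells of each library (vertical axis, percent) in each cell class or unnamed cluster (horizontal axis), with a bar per library and Wilson 95% intervals as error bars. Neutrophil-like cells were 34.4% of the adult library and 10.8% of the juvenile library, and B-like cells 9.17% and 38.6%.

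Monocyte-like cells, the blood precursors of macrophages, had far more inflammatory RNA in juveniles. CXCL10, a chemokine that draws T cells, had a log2 ratio of juveniles over adults of 4.54 (4.11 to 4.96; 9.09 to 323 CPM). ACOD1, whose enzyme makes the antimicrobial metabolite itaconate, had 4.40 (4.06 to 4.74; 22.3 to 571 CPM), and IL23A, a cytokine subunit of type 17 immunity, 4.02 (3.49 to 4.42; 2.07 to 110 CPM, from 5 adult UMIs). The cytokines IL1A (3.34), CXCL8 (2.67) and IL1B (2.48) moved with them, and the inflammatory and NF-kB list had a median of 1.57 (1.09 to 2.22), 15 of 17 members higher and the 100th percentile of random lists. The receptor TLR2 (2.11), the inflammasome sensor NLRP3 (1.32) and the high-affinity IgG receptor FCGR1A (1.35) were higher too, while TLR4 (−0.57), FCRL3 (−0.93) and C5AR1 (−0.28) were lower. Lower were also PDK4, which brakes glucose oxidation (−1.80, −2.21 to −1.40), INSIG1, a regulator of sterol synthesis (−1.59, −2.01 to −1.19), and the sterol synthesis gene HMGCS1 (−1.50, −1.84 to −1.17). The class had 200 adult and 134 juvenile cells with median depths of 11891.5 and 8597 UMIs; with a pseudocount of 20 CXCL10 was 3.56, ACOD1 3.804 and IL23A 2.56, and PDK4 was −1.14 with all cells thinned to equal depth. The inflammatory median was 0.65 in the 72 juvenile cells that carried SRY-neighbour RNA and 1.99 in the 57 that carried the RNA near CHIC1.

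Juvenile neutrophil-like cells carried more CXCL8 and immediate early RNA and less granule RNA than adult ones. CXCL8, a chemokine that recruits neutrophils, had a log2 ratio of 2.03 (1.95 to 2.11; 661 to 2719 CPM), the early growth response factor EGR1 had 1.83 (1.72 to 1.93; 443 to 1584 CPM) and the stress-induced factor MAFF 1.78 (1.47 to 2.09). MMP8 had −3.70 (−4.34 to −2.97; 140.2 to 6.14 CPM, from 6 juvenile UMIs), the sialic acid lyase gene NPL −2.98 (−3.58 to −2.19, from 4 juvenile UMIs) and the stress gene TP53INP1 −2.27 (−2.55 to −2.01). With a pseudocount of 20 MMP8 was −2.62 and NPL −1.85. The granule and immaturity list had a median of −1.83 (−3.70 to −0.39; 0 of 6 members higher), or −1.55 with LCN2, at 47 adult and 0 juvenile UMIs, set to the limit of 3 counts. Its members MMP9 (−2.73) and the granulopoiesis factor CEBPE (−1.75) were also lower. MMP8, MMP9 and LCN2 were markers used to name this class, and the adult-only cluster was led by MMP8. The cluster with most of the juvenile class had CXCL8, EGR2 and NFKBIA among its leading genes, so ratios of these genes restate part of the cluster shares. The immediate early and heat shock list was higher, at 0.82 (0.19 to 1.16; 24 of 27 members), with EGR2 at 1.69 and JUNB at 1.31. Interferon-stimulated genes had a median of 0.42 (0.23 to 0.45; 19 of 20 higher), with IFIT2 at 0.86, and the inflammatory list 0.68 (−0.36 to 1.48), with NFKBIA at 1.62 and IL1B at 1.48. MHC class I presentation genes stood at 0.29 (−0.12 to 0.59) and ribosomal protein genes at 0.21 (0.17 to 0.30). Mature neutrophil genes were near 0 (−0.01, −0.47 to 0.41), and Fc and complement receptors at −0.41 (−0.84 to 1.20), with ITGAX at −0.84 and CD55 at 1.20. The mature list was read without CXCR1, CXCR2, FPR1 and FPR2, which were not in the matrices by name.

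**Figure D2:**
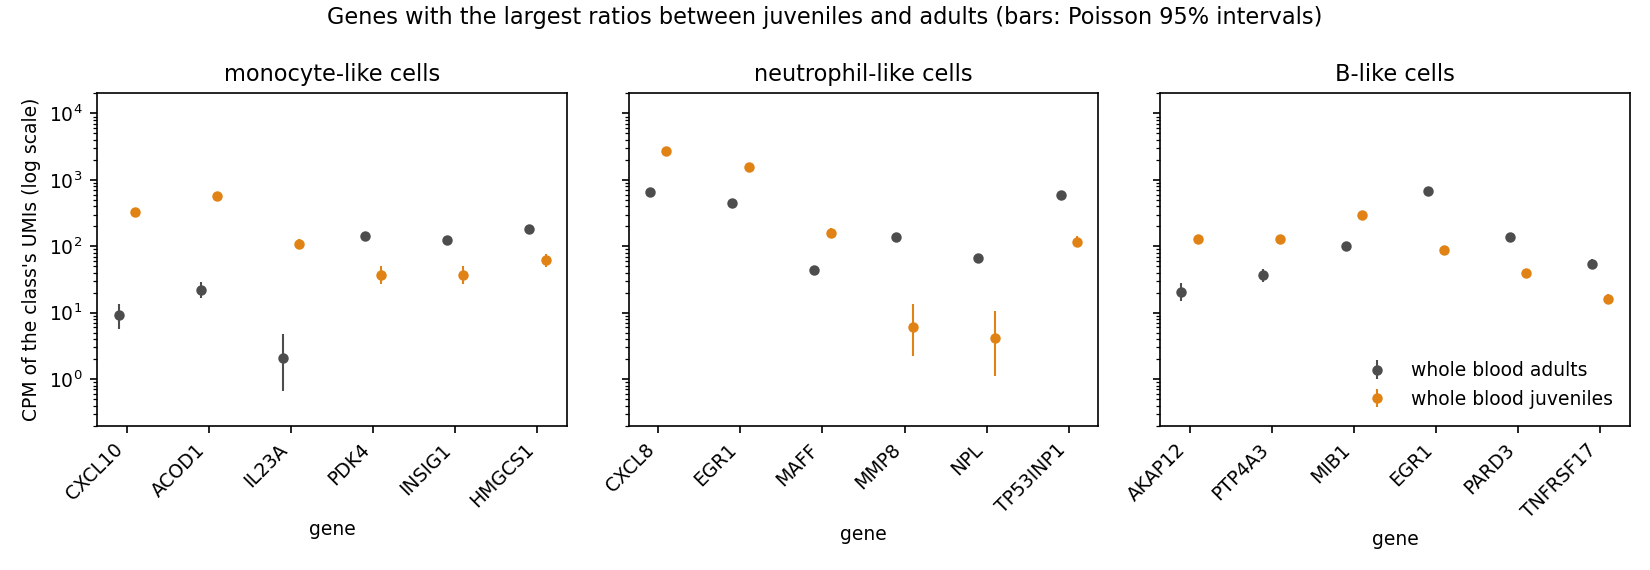
Level of the named genes in CPM (vertical axis, log scale) for monocyte-, neutrophil- and B-like cells of adults and juveniles, with exact Poisson 95% intervals as bars. CXCL10 stood at 9.09 CPM in adult and 323 CPM in juvenile monocyte-like cells, and MMP8 at 140.2 and 6.14 CPM in neutrophil-like cells.

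B-like cells of juveniles carried more AKAP12, MYB and RAG1 RNA and less EGR1 and FOS RNA than those of adults. AKAP12, a kinase anchor, had a log2 ratio of 2.35 (1.99 to 2.72; 20.8 to 127 CPM), the phosphatase gene PTP4A3 1.68 (1.38 to 1.99) and the Notch ligase gene MIB1 1.53 (1.33 to 1.72). The early B cell list had a median of 0.79 (−0.04 to 1.33; 7 of 9 higher, 100th percentile), with MYB at 1.36, the recombinase RAG1 at 1.33 and the surrogate light chain partner VPREB3, also a marker of the class, at 1.16. Proliferation genes stood at 0.45 (−0.03 to 0.75; 7 of 10 higher), with MKI67 at 1.23 and TOP2A at 0.72. EGR1 fell from 675 to 89.5 CPM (−2.85, −2.97 to −2.72), the polarity gene PARD3 had −1.66 (−1.88 to −1.45), and the plasma cell receptor TNFRSF17 had −1.48 (−1.79 to −1.17), which was −0.20 with classes called per cell. The immediate early list had a median of −0.60 (−0.82 to −0.44), with 26 of 28 members lower, FOS at −1.83 and EGR2 at −1.42; GADD45B was higher (1.52). Interferon-stimulated genes had a median of 0.18 (0.02 to 0.30; 21 of 27 higher; 0.41 with juvenile cells of the CHIC1-neighbour kind alone), with ISG15 at 0.68 and ZBP1 at −0.89. Memory and activated B cell genes went both ways (−0.16, −0.96 to 1.21), with the T-bet-associated factor ZEB2 at 1.21 and the costimulator CD80 at −0.96. MHC class II presentation genes were near 0 in B-like (0.04, −0.24 to 0.46) and monocyte-like cells (−0.04, −0.14 to 0.32). Only 7 of the 18 genes of this list were in the matrices by name, and none of them was an HLA class II chain gene. The chains themselves were thus not read.

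Subsets of the B-like class were formed with these genes among others, so their shares restate part of the ratios above. The subset led by RAG1, MYB and AKAP12 was 1.84% of adult and 9.96% of juvenile B-like cells (8.12 points, 6.12 to 9.68). Another, led by EGR1, FOS and NR4A1, was 26.5% of adult and 3.36% of juvenile B-like cells (−23.2 points, −27.3 to −19.4), and the subset led by the antibody joining chain JCHAIN, TNFRSF17 and MZB1 11.4% and 3.05% (−8.38 points, −11.6 to −5.73). The subset led by the complement receptor CR2 and KCNJ1 rose from 18.2% to 25.6% (7.46 points, 3.40 to 11.1), or by 23.2 points at subset resolution 0.4. Cells of the subset led by TPPP3 and ANXA1 were 30.8% and 32.2% of them, a difference not detectable at this depth, and cells of the subset led by ADRB1 and PLAC8 were 4.08% and 4.12%, but −7.48 points apart at subset resolution 0.4.

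T-like cells of juveniles carried less IL10 and GZMK RNA than those of adults. The anti-inflammatory cytokine IL10 had a log2 ratio of −1.37 (−1.66 to −1.09; 85.9 to 30.1 CPM), NFIA −1.25 (−1.52 to −0.99) and the kinase inhibitor gene CAMK2N1 −1.01 (−1.26 to −0.77). Higher were FAM20A (1.22, 0.97 to 1.48), the signalling regulator RGS10 (1.11, 0.87 to 1.35) and the developmental factor SOX4 (0.88, 0.58 to 1.17). With all cells thinned to equal depth NFIA was −0.58 and IL10 −2.03. Cytotoxic effector genes had a median of −0.30 (−0.46 to 0.08; 11 of 16 lower), with the granzyme GZMK at −0.76, IFNG at −0.66 and the effector factor TBX21 at −0.59. Naive and central memory genes were near 0 (−0.02, −0.18 to 0.08). Ribosomal protein genes were 0.14 (0.13 to 0.18) higher, but −0.03 among juvenile cells with the RNA near CHIC1, and nuclear oxidative phosphorylation genes 0.10 (0.06 to 0.15). Subsets of the joint T and NK family were formed with these genes among others, so their shares restate part of the ratios above. In this family, the subset led by IL10, LAG3, CD8B and IFNG was 23.0% in adults and 8.78% in juveniles (−14.2 points, −16.5 to −12.0). A subset led by TNFRSF4, CTLA4 and FOXP3, the master factor of regulatory T cells, was 16.7% and 8.63% (−8.05 points, −10.1 to −5.99). The subset led by FST and the lymph node homing receptor CCR7 was 12.3% and 12.5% of the family, at 239 and 247 cells. The subset led by CXCR3 and DPP4 went from 12.8% to 8.99% of the family (−3.80 points, −5.75 to −1.85), at 249 and 178 cells. That led by PCED1B and CMYA5 went from 5.85% to 4.44% (−1.41 points, −2.81 to −0.026), at 114 and 88 cells. All these shares are of 1948 adult and 1981 juvenile T and NK cells, among which a GNLY-led subset rose by 24.4 points. Such a rise lowers the shares of the other subsets. The T-like class had 1432 and 957 cells. Shares among T-like cells were not calculated, so no fall of these 2 subsets within T-like cells is shown.

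In NK-like cells the granzyme GZMM (1.30, 1.16 to 1.43; 306 to 758 CPM), the serine protease gene PRSS57 (1.28, 1.05 to 1.52) and the antiviral GTPase MX1 (0.89, 0.64 to 1.13) were higher in juveniles. STMN1, a microtubule regulator of dividing cells (−1.39, −1.71 to −1.08), the genome stability gene RMI2 (−1.37; 65.9 to 22.4 CPM) and the lysosomal gene LAPTM5 (−1.30, −1.41 to −1.19) were lower. The inflammatory list had a median of −0.75 (−1.59 to 0.09; 6 of 7 lower), with IL10 at −1.59 and NFKBIA at −0.82, and the immediate early list −0.21 (−0.30 to −0.03; 17 of 23 lower), with KLF6 at −0.61. Cytotoxic effector genes were near 0 as a list (−0.08, −0.25 to 0.14), with KLRG1, a receptor of terminal differentiation, at −1.12. A subset led by GNLY, GNGT2 and PTGIS was 6.31% of the T and NK family in adults and 30.7% in juveniles (24.4 points, 22.1 to 26.7), so it held mostly juvenile cells. The GNLY-led subset with NCR2 fell from 6.26% to 3.43% (−2.83 points, −4.20 to −1.49), and the GNLY-led subset with HSPB1 stayed at 11.5% and 11.2%. GNLY-led subsets also carried the T cell receptor component CD3E at 1008, 1114 and 1127 CPM, beside 931 CPM in the subset with FOXP3. The largest of them, with HSPB1 and GZMM, had CD3D at 275 CPM and CD8B at 174 CPM, close to the CD3D of the FOXP3 subset (283 CPM), while the other two had CD3D at 26.2 and 44.4 CPM.

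**Figure D3:**
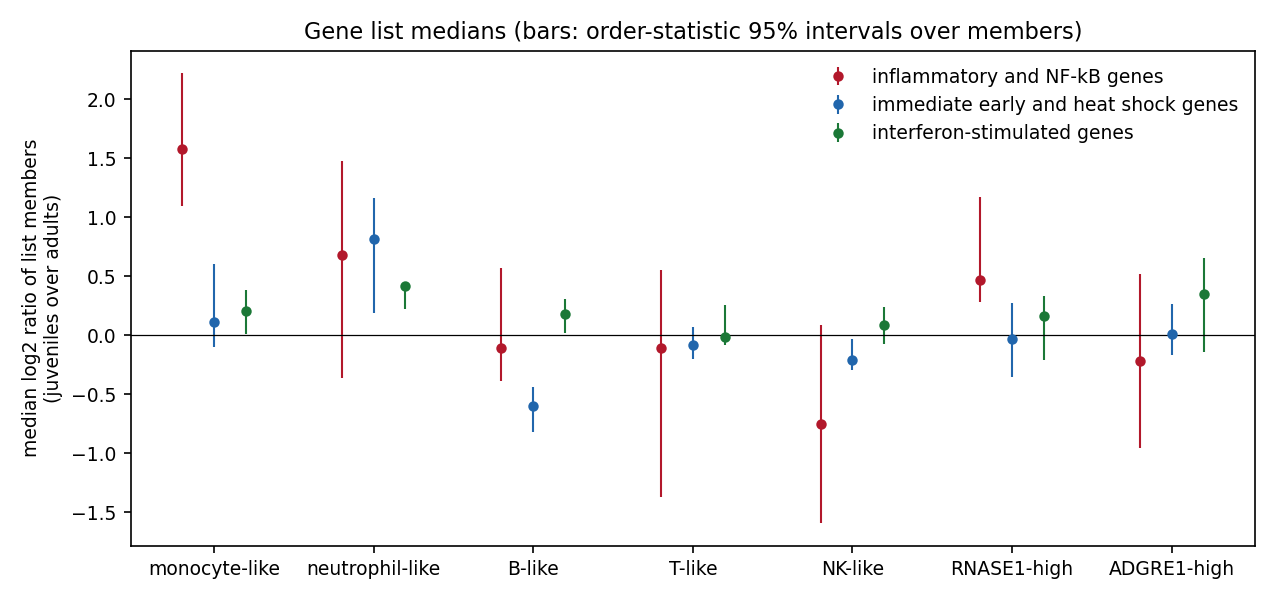
Median log2 ratio of juveniles over adults (vertical axis) of the inflammatory, immediate early and interferon-stimulated gene lists per cell class or cluster (horizontal axis), with order-statistic 95% intervals over list members as bars. The inflammatory list stood at 1.57 in monocyte-like cells, and the immediate early list at 0.82 in neutrophil-like and −0.60 in B-like cells.

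Some clusters were left without a class. The RNASE1-high cluster, with the lipase LPL and the activation receptor TNFRSF8 among its leading genes, was 3.11% of adult and 2.38% of juvenile cells (−0.730 points, −1.35 to −0.125), and an estimated 1.06% of juvenile cells of the CHIC1-neighbour kind. Its inflammatory list was higher in juveniles (0.47, 0.28 to 1.17; 12 of 13 higher; 1.75 in the 18 juvenile cells of the CHIC1-neighbour kind), with IL1B at 2.37 and TNF at 1.06. PXYLP1 (2.89, 1.95 to 3.66, from 4 adult UMIs), the microRNA processor DROSHA (1.78, 0.92 to 2.60) and the activation marker CD83 (1.72, 1.29 to 2.16) led its rises. The macrophage protein gene CD5L (−2.64, −3.47 to −1.77), IFI6 (−1.77, −2.65 to −0.86) and the stress gene DDIT4 (−1.61, −1.93 to −1.29) led its falls; the complement receptor C5AR1 was at −2.35. PXYLP1 was 1.83 with a pseudocount of 20, and with cells thinned to equal depth CD83 was 0.87, IFI6 −3.95 and DDIT4 −2.25. Thinning leaves fewer UMIs, and IFI6 had only 42 adult and 7 juvenile UMIs before it, so counting error may account for such moves.

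The ADGRE1-high cluster, whose best score was eosinophil but with only 2 markers, was 4.90% of adult and 7.93% of juvenile cells (3.03 points, 2.13 to 3.94). CNOT3 (2.11, 0.73 to 3.50, from 3 adult UMIs), DTNB (1.96, 0.69 to 3.29) and PNPLA6 (1.69, 0.51 to 2.97) were higher, and SP3 (−1.10, −1.82 to −0.39) and the prostaglandin receptor PTGER4 (−1.08, −1.73 to −0.42) lower. Its pattern recognition receptors had a median of −1.17 (−1.99 to 0.27), or −0.96 with members at 0 UMIs set to the limit. Its interferon-stimulated genes stood at 0.35 (−0.14 to 0.65) and its cells had median depths of 709 and 765 UMIs. The PTGS2-high cluster, with median depths of 635.5 and 627 UMIs, was 5.84% of adult and 2.24% of juvenile cells (−3.60 points, −4.35 to −2.87), and an estimated 0.432% of juvenile cells of the CHIC1-neighbour kind. Its best score was neutrophil (0.861, 6 markers). Low depth without a neutrophil marker among its leading genes kept it unnamed, so it may hold neutrophils that the neutrophil-like class leaves out. TMM scaling shifted all its log2 ratios by −0.18. Higher in juveniles were NSUN6 (1.97, 1.35 to 2.61), IL15 (1.78, 0.96 to 2.61) and FOS (1.55, 1.27 to 1.83). Lower were USP11 (−2.89, −4.77 to −1.18) and SSH1 (−2.64, −4.52 to −0.91), each with 2 juvenile UMIs, and TP53INP1 (−2.37, −3.18 to −1.66). Immediate early genes there had a median of 0.62, inflammatory genes 0.61 and ribosomal protein genes 0.44. MHC class I genes stood at 0.67 and interferon-stimulated genes at 0.19, or 0.59 and −0.02 with members at 0 UMIs set to the limit. Fc and complement receptors stood at 0.15, or −0.24 with that limit and −0.03 with TMM scaling. The ABCA8-high cluster was 1.93% of adult and 1.23% of juvenile cells, 1.64% of mixed-age whole blood and 2.77% of PBMC.

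The inflammatory list was at −0.10 in B-like, −0.11 in T-like and −0.22 in ADGRE1-high cells, and the immediate early list at 0.11 in monocyte-like, −0.08 in T-like, −0.03 in RNASE1-high and 0.01 in ADGRE1-high cells. In the remaining classes, interferon-stimulated genes had medians of 0.21 in monocyte-like, 0.09 in NK-like, −0.01 in T-like and 0.16 in RNASE1-high cells. MHC class I presentation genes had 0.19 in monocyte-like, 0.14 in T-like, 0.07 in NK-like and 0.20 in RNASE1-high cells. Pattern recognition receptors had 0.13 in monocyte-like, 0.04 in neutrophil-like, 0.01 in B-like (−0.29 with members of at least 50 CPM), 0.10 in NK-like and −0.03 in T-like cells, with TLR3 at −0.77 in B-like cells. Fc and complement receptors had −0.32 in B-like, 0.11 in NK-like and −0.07 in monocyte-like cells. Proliferation genes had 0.24 in T-like and 0.01 in NK-like cells, ribosomal protein genes 0.11 in NK-like and 0.02 in B-like cells, and oxidative phosphorylation genes 0.03 in NK-like and −0.03 in B-like and monocyte-like cells. Neutrophil markers read in other cells, among them S100A8, S100A9 and S100A12, were lower in juveniles in B-like (−2.24), T-like (−1.87, −2.11 to 1.59), NK-like (−1.48), ADGRE1-high (−1.29), RNASE1-high (−1.17) and PTGS2-high cells (−0.36), and went both ways in monocyte-like cells (−0.54, −0.89 to 1.83; 3 of 7 members higher). The whole adult library had 15387 CPM of these markers and the whole juvenile library 3025 CPM. Erythroid and platelet markers had too few members with a CPM of 10 for a value in any class.

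PBMC, collected from a density gradient, a step that pellets granulocytes, had almost no neutrophil-like cells and a higher NK-like share than whole blood. Neutrophil-like cells were 10.1% (9.18 to 11.1%) of whole blood and 0.196% (0.109 to 0.350%) of PBMC of the same animals, a difference of −9.88 points (−10.9 to −8.97). NK-like cells were 21.3% (20.0 to 22.6%) and 44.3% (43.0 to 45.6%), a difference of 23.0 points (21.1 to 24.8). T-like cells were lower in PBMC, at 6.58% against 13.4% (−6.78 points, −8.04 to −5.55), as were B-like cells, at 27.0% against 32.1% (−5.08 points, −6.94 to −3.22). The NK-like and T-like differences depend on how the subset led by GNLY, HSPB1 and GZMM is counted. It had CD3D at 275 and CD8B at 174 CPM, with 405 of 1372 T and NK cells in whole blood and 1254 of 2860 in PBMC. Only 370 PBMC cells were T-like, so most of this subset there was counted as NK-like. Shares with it counted as T-like were not calculated. Monocyte-like cells were 4.45% of whole blood and 1.14% of PBMC (−3.31 points, −4.04 to −2.63), but 2.04 points higher in PBMC with classes called per cell and −0.308 with each library clustered alone. Conventional dendritic-like cells were 0.429% and 1.53% (1.10 points, 0.713 to 1.49), but −0.628 with each library clustered alone, 2.11 without a cell filter, 2.13 with at least 500 genes and 5.01 with classes called per cell. Plasmacytoid dendritic-like cells were 0.126% and 0.160%, not a detectable difference. RNASE1-high cells rose from 8.84% to 15.9% (7.04 points, 5.73 to 8.33) and ABCA8-high cells by 1.13 points (0.535 to 1.71), while ADGRE1-high cells fell from 5.68% to 0.427% (−5.26 points, −6.03 to −4.55; −2.90 with at least 500 genes per cell) and PTGS2-high cells from 2.00% to 0.0178% (−1.98 points, −2.46 to −1.58). Among cells that were not neutrophil-like, the differences were 20.7 points for NK-like, −8.27 for T-like, −8.62 for B-like, −3.80 for monocyte-like and 6.08 for RNASE1-high cells. With ADGRE1-high and PTGS2-high cells also left out of the denominator they were 18.7 for NK-like, −9.63 for T-like and −11.8 for B-like cells. Both libraries had lost platelets by sorting, and whole blood also its red cells by lysis. At resolution 0.5 the T-like and monocyte-like differences were −3.95 and −2.18 points, and with each library clustered alone the T-like difference was −4.39.

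In B-like cells the antibody joining chain JCHAIN had a log2 ratio of PBMC over whole blood of 2.05 (1.90 to 2.19), but −0.45 with classes called per cell and 1.37 with cells thinned. The orphan nuclear receptor NR4A1 had 1.08 (0.96 to 1.20), the ciliary gene TMEM107 −3.59 (−3.75 to −3.43; 735 to 56.6 CPM) and the transcriptional corepressor ATN1 −1.52 (−1.72 to −1.32). ATN1 was also lower in NK-like cells (−1.76, −1.98 to −1.55), with ZNF608 (−0.99, −1.27 to −0.70), while STMN1 (0.81, 0.51 to 1.12) and EMC6 (0.72, 0.52 to 0.91) were higher. Thinning moved ZNF608 to −0.52, STMN1 to 0.43 and EMC6 to 1.14. In T-like cells the differentiation inhibitor ID4 (1.88, 1.57 to 2.20) and ADIRF (1.65, 1.23 to 2.08) were higher, and the checkpoint receptor CTLA4 (−1.54, −1.92 to −1.16) and the costimulator TNFRSF4 (−1.36, −1.78 to −0.95) lower. With classes called per cell ID4 was 1.30, ADIRF 0.97, CTLA4 −2.35 and TNFRSF4 −1.94. In RNASE1-high cells CITED4 (0.84, 0.50 to 1.20) and DMKN (0.80, 0.42 to 1.19) were higher, and ABHD13 (−0.69, −1.03 to −0.36) and the interferon-induced ligase gene DTX3L (−0.69, −0.97 to −0.41) lower; ABHD13 was 0.16 with cells thinned. The typical size of a ratio, its median without sign, was 0.109 in B-like and 0.193 in T-like cells, against 0.142 and 0.125 in the age comparison. In NK-like and RNASE1-high cells it was 0.182 and 0.116, against 0.130 and 0.220. Counting error raises this size and the UMI totals of the comparisons were unlike, so it does not rank them.

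Immediate early genes were higher in PBMC B-like cells (median 0.32, −0.11 to 0.73; 18 of 27 higher), with EGR1 at 1.02 and JUN at 0.92. They were lower in NK-like (−0.23, −0.44 to −0.04; 19 of 23 lower) and T-like cells (−0.21, −0.34 to 0.11). Interferon-stimulated genes were lower in T-like cells (−0.27, −0.36 to −0.13; 22 of 25 lower) and RNASE1-high cells (−0.15, −0.25 to −0.0025). T-like cells of PBMC also had less of IFNG (−1.13), with list medians of −0.15 for cytotoxic, −0.12 for naive and central memory, −0.35 for proliferation and 0.37 for Fc and complement receptor genes. In NK-like cells TMM scaling shifted all log2 ratios by 0.13. Before that shift, ribosomal protein genes had a median of 0.18 (0.16 to 0.22), oxidative phosphorylation genes 0.19 (0.12 to 0.22), cytotoxic genes 0.03, MHC class I genes 0.01 and interferon-stimulated genes −0.14. B-like cells had medians of −0.09 for MHC class II, −0.06 for MHC class I, −0.13 for early B cell, 0.0044 for memory B cell, −0.18 for inflammatory, −0.18 for proliferation and −0.15 for pattern recognition receptor genes. RNASE1-high cells had 0.13 for inflammatory genes (9 of 12 higher, TNF 0.81). Neutrophil markers read in other cells were lower in PBMC, at −1.80 in RNASE1-high and −2.08 in T-like cells, the latter −1.81 with members at 0 UMIs set to the limit.

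Subset shares also differed between PBMC and whole blood, and they restate part of the gene ratios above, since subsets were formed with those genes among others. In the T and NK family, the subset led by GNLY, GNGT2 and NCR2, a natural cytotoxicity receptor, was 21.2% of whole blood and 36.1% of PBMC cells (14.9 points, 12.1 to 17.6). A further subset led by GNLY, HSPB1 and GZMM was 29.5% and 43.8% (14.3 points, 11.3 to 17.3), or 29.0 points more at subset resolution 0.4. The CCR7-led subset fell from 10.7% to 2.87% (−7.85 points, −9.68 to −6.18) and the subset led by the chemokine receptor CXCR3 and DPP4 from 7.80% to 1.54% (−6.26 points, −7.85 to −4.86). Rises of the GNLY-led subsets lower the shares of the others in this family, and shares among T-like cells were not calculated. Among B-like cells the subset led by EGR1 and FOS rose from 15.1% to 27.7% (12.6 points, 9.57 to 15.6) and the subset led by ADRB1 and PLAC8 from 31.3% to 43.6% (12.2 points, 8.65 to 15.8). The CR2-led subset fell from 20.8% to 12.3% (−8.47 points, −11.3 to −5.71), or by −17.6 points at subset resolution 0.4, and the subset led by KCTD1 and BCL6 from 11.6% to 2.70%. Smaller falls were seen in the B-like subsets led by TPPP3 and ANXA1 (−5.13 points, −7.06 to −3.28) and by RAG1 and MYB (−2.09 points, −3.43 to −0.855). In the T and NK family the subset led by IL10 and LAG3 was lower (−2.72 points, −4.20 to −1.40; −8.91 at subset resolution 0.4), as was the subset led by TAL1 and CD7 (−1.68 points, −3.01 to −0.516).

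Receptors and integrins were spread unevenly over the classes, read as the lowest and highest CPM over libraries with at least 100 cells of a class. Conventional and plasmacytoid dendritic-like cells fell short of 100 cells in every library, so they were not part of this reading. ITGAM, the myeloid integrin chain of complement receptor binding, was highest in ADGRE1-high (675 to 777 CPM), RNASE1-high (548 to 764 CPM) and neutrophil-like cells (389 to 520 CPM) and reached 3.90 CPM in NK-like cells. ITGAX, a dendritic cell integrin in mice, was highest in NK-like cells (144 to 192 CPM), and the mannose receptor MRC1 in ABCA8-high (41.7 to 65.0 CPM) and RNASE1-high cells (18.5 to 56.8 CPM). The lipopolysaccharide receptor TLR4 was highest in PTGS2-high (872 to 943 CPM) and neutrophil-like cells (433 to 625 CPM), TLR8 in RNASE1-high cells (155 to 272 CPM) and TLR10 in B-like cells (72.2 to 106 CPM). TLR7 stood at 42.7 to 86.4 CPM in RNASE1-high and 30.7 to 59.0 CPM in neutrophil-like cells. TLR2 stood at 35.9 to 171 CPM in monocyte-like and 45.9 to 56.8 CPM in B-like cells. The double-stranded RNA sensor TLR3 stood at 45.7 to 108 CPM in B-like, 50.5 to 104 CPM in NK-like and 25.2 to 62.7 CPM in T-like cells. The flagellin receptor TLR5 stood at no more than 0.413 CPM in any class that was read. MX1 was high in T-like (196 to 245 CPM) and B-like cells (172 to 207 CPM) and at most 6.14 CPM in neutrophil-like cells, where the antiviral gene SAMD9L reached 674 to 971 CPM. The DNA-sensing adaptor STING1 stood at 54.5 to 90.2 CPM in T-like and at most 4.85 CPM in neutrophil-like cells. FCGR1A was higher in neutrophil-like (179 to 298 CPM) than in monocyte-like cells (6.61 to 24.7 CPM). No gene was called CD4, TLR1, TLR6 or TLR9 in the matrices.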

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

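Of these tests the handling test was chosen only after the result was seen, and the B-like subset test was repeated in another form after its first value. The test by kind of juvenile cell uses a split that was itself chosen after the data had been seen.

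Barcodes with under 200 genes lay outside every comparison: 76 in adults, 63 in juveniles, 105 in whole blood of mixed ages and 23 in PBMC. They were singled out because they carried a signal in data set aside. Haemoglobin cluster genes made up 94.8%, 95.9%, 95.1% and 81.0% of their UMIs, at median depths of 3167.5, 3052, 3088 and 621 UMIs, against 0.152%, 0.104%, 0.0673% and 0.174% in the kept cells. No explanation was tested.

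Immediate early and heat shock genes differed between the adult and juvenile libraries in opposite ways by class, with a median of 0.82 in neutrophil-like, −0.60 in B-like and −0.21 in NK-like cells. The difference between the classes was not tested. Handling that moved all cells of a library alike would give both classes a like sign, and the intervals of 0.19 to 1.16 and −0.82 to −0.44 lay on opposite sides of 0, which argues against it as the whole cause, though the pattern was singled out for these opposite signs; handling that acts differently on each class stays open. A shift between B-like subsets may carry part of the fall, since the list median was −0.18 (−0.29 to 0.07; 698 juvenile cells) in the subset of closest share (28.0% and 30.9%) when subsets were formed without the list's genes. That test first gave −0.13 (−0.35 to 0.03) with subsets formed with those genes. Other B-like subsets formed without them ranged from −0.68 to 0.06. A like test was not made within neutrophil-like clusters. The cluster with EGR2, IER2 and ATF3 among its leading genes held 520 of 631 juvenile and 262 of 1839 adult neutrophil-like cells. A shift between clusters thus stays open for the rise in that class. By kind of juvenile cell the B-like median was −0.50 (−0.72 to −0.28; 763 cells) in the CHIC1-neighbour kind and −0.73 (−1.23 to −0.38; 1257 cells) in the other, too close to decide whether a single kind of animal was the source; age stays open and untested.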

How the results depend on the processing

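Chosen after the data were seen were 3 settings: juvenile cells of the CHIC1-neighbour kind alone, SRY- and CHIC1-neighbour genes kept in clustering, and the wider denominator; the rest were planned. No paired analysis was possible because each group was 1 library.

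Of the share values under other settings, 123 stayed inside the interval of the reported value, 41 moved outside it and 3 turned in direction where that interval left out 0; for named genes the numbers were 362, 56 and 2, for gene lists 529, 27 and 1, for subsets 56, 12 and 0 and for levels across classes 67, 5 and 0. Moved values whose reported interval held 0 changed sign in places too. Conventional dendritic-like cells, juveniles minus adults, were at −0.515 points without a cell filter and −0.635 at 500 genes or more, and plasmacytoid ones, PBMC minus whole blood, at −0.292 with classes called per cell. With juvenile cells of the CHIC1-neighbour kind alone, immediate early genes were at −0.24 in monocyte-like (57 cells), 0.30 in T-like and 0.57 in RNASE1-high cells (18 cells), and interferon-stimulated genes at 0.27 in T-like cells. Clustering at resolution 2 and clustering with the SRY and CHIC1 neighbours left all 22 share values each inside their intervals. Where a cause is not named below, the cause was not tested.

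For juveniles minus adults, at least 500 genes per cell gave −27.0 points for neutrophil-like and 31.4 for B-like cells. Resolution 0.5 gave −27.2 for neutrophil-like, −2.15 for monocyte-like and −3.68 for T-like cells; it left clusters of T-like cells unnamed. Classes called per cell gave −26.8 for neutrophil-like, −2.38 for monocyte-like and 20.3 for B-like cells. Juvenile cells of the CHIC1-neighbour kind alone gave −33.0 for neutrophil-like, −0.376 for monocyte-like, −12.8 for T-like, 20.8 for NK-like and 35.9 for B-like cells, and turned the ADGRE1-high difference to −3.19 and ribosomal protein genes in T-like cells (T cell) to −0.030. That setting depends on how often the RNA was found per class, in 98.5% of adult monocyte-like and 26.3% of adult ADGRE1-high cells. Estimated with these rates, ADGRE1-high cells were 5.46% (at most 7.72%) of juvenile cells of that kind against 4.92% of adult cells, so the turn to −3.19 rests on how often the RNA was found.

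For PBMC minus whole blood, resolution 0.5 gave −11.9 for neutrophil-like, −2.18 for monocyte-like and −3.95 for T-like cells. Each library clustered alone gave −11.9, −0.308 and −4.39 for these classes and turned conventional dendritic-like cells to −0.628. Classes called per cell gave −13.0 for neutrophil-like, −3.46 for T-like and 16.975 for NK-like cells, and turned monocyte-like cells to 2.04 and JCHAIN in B-like cells to −0.45. At least 500 genes gave −7.03 for B-like cells. Thinning turned ABHD13 in RNASE1-high cells to 0.16.

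Thinning moved 27 of 64 named genes outside their intervals and turned 1 more, ABHD13, in direction. Thinned values rest on 500 UMIs per cell and were given no interval, so counting error may account for part of these moves. A pseudocount of 20 moved 15, and TMM factors and subtraction of outside RNA moved none of these 64. The rule for named genes had left out genes much higher in another class, so subtraction could change their higher level only little. Classes called per cell gave no value for the unnamed clusters, and resolution 0.5, at least 500 genes, no filter, doublets kept and clustering alone gave none for some clusters. The list alternatives gave none where fewer than 3 members were left. Depth limits the ADGRE1-high and PTGS2-high clusters most, at 201215 adult and 381986 juvenile UMIs and at 212190 and 89464, and dendritic-like cells, of which 17 conventional and 6 plasmacytoid ones were kept in adults.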

Other observations

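Chosen only after the result was seen were the sex test and the test of other animal differences. The other tests of this part were chosen before. Among them, the test of a single kind of animal rests on a split of juvenile cells made after the data had been seen.

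Some innate genes were high in both neutrophil-like and PTGS2-high cells, a cluster whose best score was neutrophil. Dendritic-like cells were too few to be read for these genes. The receptor FCGR1A stood at 179 to 298 CPM in neutrophil-like and 335 to 396 CPM in PTGS2-high cells, the inflammasome adaptor NLRC4 at 92.1 to 193 CPM and 145 to 250 CPM, and the C-type lectin CLEC4E, a receptor of mycobacterial lipids, at 1216 to 1563 CPM in neutrophil-like and 382 to 950.1 CPM in PTGS2-high cells against 231 to 290 CPM in monocyte-like cells, whose list of markers it belongs to. The complement receptor C5AR1 was highest in neutrophil-like cells (1714 to 3923 CPM). ADGRE1-high cells had the most of the adaptor MYD88 (416 to 615 CPM) and of the anaphylatoxin receptor C3AR1 (44.7 to 123 CPM). RNASE1-high cells carried the Fc receptor chain FCER1G (2860 to 4367 CPM) and the virus-tethering gene BST2 (162 to 218 CPM), and NK-like cells carried FCER1G at 3139 to 4333 CPM. The inflammasome gene NLRP3 was highest in monocyte-like cells (71.9 to 187 CPM) and had 0 UMIs in ADGRE1-high cells, whose depth was low.

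A small T-like subset led by ID4, PI3 and ADIRF had little CD8A (6.45 CPM) and CD8B (4.30 CPM) and was 1.85% of the T and NK family in adults, 2.73% in juveniles, 3.79% in mixed-age whole blood and 4.93% in PBMC.

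RNA of 9 genes near SRY was at 0.169 CPM in adults, 1426 in juveniles, 1685 in whole blood of mixed ages and 1505 in PBMC, and a non-coding RNA near CHIC1 was at 1039, 391, 207 and 208 CPM. With the most widely found SRY neighbour set aside, 1693 juvenile cells were called of the CHIC1-neighbour kind; 3283 were called of the SRY-neighbour kind, and 872 were not called, 76 of them with both.

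The higher neutrophil-like share of adults was weighed against 3 explanations. If the sex of the animals were the source, juvenile cells of the CHIC1-neighbour kind, which the adult cells resemble in that RNA, would be rich in neutrophil-like cells; their estimated share was 1.64% (at most 2.42%) against 34.6% in adults, which argues against it, if the RNA is found as often in juvenile as in adult cells of a class. Without cell filters the difference was −22.6 points, against −23.6; the filters had taken only 76 and 104 adult and 63 and 164 juvenile barcodes (few genes, high mitochondrial share), too few to make such a difference, while the limit of 500 UMIs in the deposited matrices was not tested. The estimated share differed by 14.1 points between both kinds of juvenile cells (15.8% and 1.64%). These kinds are split by the same RNAs as in the sex test, so the spread cannot tell sex from other differences between animals. The juvenile library pooled 3 animals, so 1 of the kinds came from a single animal if each animal gave cells of 1 kind only. Which kind that was is unknown, and this limits the sex test too. Other differences between animals than age remain a candidate explanation. Age itself stays open and untested.

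The higher inflammatory RNA of juvenile monocyte-like cells, a median of 1.57, was also weighed. Subtraction of the library profile left 1.59 (1.14 to 2.23), which argues against RNA from other cells. Thinning all cells to equal depth left 2.11 (1.60 to 2.76, 134 juvenile cells), which argues against the larger weight of deep cells as the source. Levels were already scaled to equal totals, so thinning could not test other effects of depth. Part of it may come from a single kind of animal, since the median was 0.65 (0.32 to 1.01; 72 cells) in the SRY-neighbour kind and 1.99 (1.38 to 3.06; 57 cells) in the other. Age stays open here too, untested.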
